A study of Homo sapiens with 12 samples.

How the data were processed

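The intensities are those the authors deposited, 1 linear value per probe set and array, for 54675 probe sets of the HG-U133_Plus_2 array on each of 12 arrays. Per the submitters' processing notes they were made with GCOS 1.2, and the array type is given per the file headers of the array experiment files. The summary algorithm and the scaling target are not given in the sources used here. The values themselves showed that each array had been scaled, since the mean without the top and bottom 2% of the values was the same on all 12, and no further normalization between arrays was applied. The table held no detection calls and 0 columns of other samples. No genome build or coordinates came with it, so that genes are given by symbol and probe set only.

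Intensities were taken as log2(value + 60.6), where 60.6 is the 20th percentile of the table, so that the log2 fold changes given by limma are on this scale and understate the changes of dim genes. The 62 control probe sets were left out, as were 95 probe sets of XIST and of Y-linked genes, because their levels are not reported for human samples. A probe set was kept when its value was above the median of its own array on at least 3 of 12 arrays, which left 31891. Of these 26137 named 1 gene, 1227 named several and 4527 named none. Each gene was represented by the single-gene probe set with the highest mean, which gave 13475 genes, of which 6835 had more than 1 kept probe set. In the galectin-1 and vehicle comparison 5 genes, and in the LPS and untreated comparison 7 genes, had probe sets called in opposite directions; in galectin-1 against untreated there were 2, and in the other comparisons 0.

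The groups were compared with limma 3.58.1 in R 4.3.3, by 1 fit of 4 group means with variances moderated along an intensity trend (prior degrees of freedom 4.27, residual 8). A gene was called at an adjusted p under 0.05 by Benjamini-Hochberg over all genes of a comparison, and each ± beside a log2 fold change is limma's standard error. Without any difference, a share of about 0.05 of the genes tested would have an unadjusted p under 0.05. Vehicle was taken as the control of galectin-1, and untreated cells as the control of LPS, for which the labels give no separate vehicle. The labels do not say what the vehicle was. Replicates are donors, and the labels give the same 3 donor numbers in every group. The expression values bore the numbers out as pairs: after the group means were taken away, the 18 same-numbered pairs of arrays correlated across genes with r = 0.0916 to 0.289 (median 0.146), against -0.221 to 0.00365 for the 36 pairs with different numbers, and each of the 12 arrays matched its own number best. Without group means the deviations cancel within each group. Negative values for different numbers thus follow from positive ones for the same numbers and are no separate contrast. The fit holds no donor block, which was planned as an alternative, and the blocked values are given where they change a call.

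Gene groups were tested with camera on 29 fixed lists, 22 of dendritic cell biology and 7 of markers of other blood cells, with a preset correlation of 0.01 between members and adjustment over all 174 tests of 6 contrasts. A second test estimated the correlation from the residuals. The lists were maturation markers, uptake receptors of immature cells, the CD1 family, chemokines, cytokines, NF-kB feedback and targets, interferon-stimulated genes, class II and class I presentation, matrix proteases and inhibitors, adhesion and migration, cholesterol synthesis, NRF2 oxidative stress, metallothioneins, the unfolded protein response, heat shock, glycolysis and hypoxia, the cell cycle, galectins, eicosanoid and tryptophan enzymes, regulators of T cells and transcription factors, with T cell, B cell, NK cell, monocyte and macrophage, neutrophil, platelet and erythroid markers. Genes are named by a fixed rule: in each comparison the 12 largest rises and 12 largest falls among called genes with the same sign in the 3 same-numbered pairs, up to 4 members of each list with the smallest adjusted p, the 5 smallest p where nothing was called, and LGALS1 and TLR4 always. The text gives a part of the genes this rule names. The groups, comparisons, filter, tests, lists, naming rule and alternative settings were chosen before the data were examined, apart from the alternatives said to be added afterwards.

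The alternatives were a donor block, fixed or random, a pseudocount of 1 or of the median, no filter or a stricter one, quantile normalization, median centring, the mean of a gene's probe sets, only the 2 groups compared, no intensity trend, array weights, the fluidics station as a block, a 2-fold minimum, an estimated correlation in camera, and leaving out each array in turn. The station is given per the file headers of the array experiment files: the 3 untreated arrays and LPS replicate 1 on a first station, LPS replicates 2 and 3 and galectin-1 replicates 1 and 2 on a second, and no station for galectin-1 replicate 3 and the 3 vehicle arrays, which the block took as a station of their own. In a test with known changes, the values of each gene were drawn at random around its untreated mean, with its real residual spread. In the galectin-1 arrays 50 genes each were raised or lowered by a known size. Of these 3 were called at a log2 change of 0.5, 18 at 1, 41 at 2 and 48 at 4. There 6 unchanged genes were called, 5.17% of the calls, with 0 calls in the LPS and vehicle comparisons. By camera 0 of 29 unchanged lists passed, and a list of 20 genes, 10 of them raised, passed with adjusted p = 4.49e-07. The genes were drawn independently of each other, so that the test cannot show how often lists of correlated genes pass without a change.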

Results

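Human monocyte-derived dendritic cells, antigen-presenting cells that develop from blood monocytes in culture, were profiled on 12 whole-genome oligonucleotide arrays. The arrays formed 4 groups of 3: untreated immature cells, cells given vehicle only, cells given galectin-1, and cells given lipopolysaccharide (LPS). Galectin-1 is a secreted lectin that binds galactose-containing glycans and is the product of LGALS1. LPS, the endotoxin of Gram-negative bacteria, is sensed through TLR4 and is a standard stimulus for dendritic cell maturation, the change from antigen-sampling cells to cells that activate T cells. Each group held 3 donors, 1 array each, with the same donor numbers in every group. The deposited intensities had the same 2% trimmed mean on all 12 arrays, and the median intensity of an array lay between 288.1 and 350.6. The group means of that median were 339.2 ± 15.8 (SD, n = 3) in untreated, 297.4 ± 14.2 in vehicle, 323.6 ± 18.2 in galectin-1 and 324.5 ± 20.5 in LPS arrays. The ratio of the 3' to the 5' control probe set of GAPDH, a measure of RNA integrity, was 1.00 ± 0.0189 (SD, n = 3) in untreated, 1.03 ± 0.0328 in vehicle, 1.06 ± 0.0469 in galectin-1 and 1.07 ± 0.0276 in LPS arrays. The ratio of ACTB was 1.03, 1.04, 1.03 and 1.03. Across the 13475 genes tested, the correlation between pairs of arrays ran from r = 0.888 to 0.969, and the first principal component held 44.7% of the variance. The number of arrays, 3 per group, limits the precision of every value given here.

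The comparison of galectin-1 with vehicle asks which transcripts changed with galectin-1 against the control given vehicle only. IDO1, the enzyme that starts tryptophan breakdown along the kynurenine pathway, rose 105.5-fold (log2 fold change 6.72 ± 0.56, standard error, n = 3 per group, adjusted p = 4.3e-05). The inflammatory cytokine IL1B rose 81.2-fold (6.34 ± 0.74, adjusted p = 4.21e-04) and CCL5, a chemokine that attracts T cells and monocytes, rose 84.6-fold (6.40 ± 0.47, adjusted p = 1.79e-05). SELENOP, a secreted selenium carrier, fell by 7.15 ± 1.42 on the log2 scale, a 141.6-fold difference (adjusted p = 0.00633), and TLR4, the receptor for LPS, fell by 1.90 ± 0.27 (adjusted p = 0.00128). LGALS1, which encodes galectin-1 itself, differed by -0.01 ± 0.08 (adjusted p = 0.949).

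In all, 2301 of 13475 genes (17.1%) passed an adjusted p of 0.05 in the galectin-1 comparison, 1022 higher and 1279 lower, and 1192 of them differed by at least 2-fold, 612 higher and 580 lower. At an unadjusted p under 0.05 there were 4139. The excess of falls depended on scaling and samples, with 1027 higher and 1109 lower when the arrays were centred on their medians, and 606 and 513 without vehicle replicate 3. The 12 largest rises also held IL12B, a subunit of cytokines that drive T helper cells (6.46 ± 0.93, adjusted p = 0.00125), TNFAIP6, a secreted hyaluronan-binding protein (6.46 ± 0.29, adjusted p = 4.48e-07), and IL2RA, a receptor chain for a T cell growth factor (6.33 ± 0.96, adjusted p = 0.0016). EBI3, a subunit of heterodimeric cytokines, rose by 6.07 ± 0.45 and INHBA, a subunit of activin, by 5.76 ± 0.36. The ectoenzyme CD38 rose by 5.53 ± 0.42, and the integrin chains ITGB8 and ITGB3 by 6.12 ± 0.62 and 5.76 ± 0.84. Among the 12 largest falls were the potassium channel KCNJ5 (-5.45 ± 1.19, adjusted p = 0.00952), the adenosine receptor ADORA3 (-4.45 ± 0.82, adjusted p = 0.0046), the nucleotide receptor P2RY13 (-4.21 ± 0.84, adjusted p = 0.00653) and HAMP, which encodes the iron hormone hepcidin (-3.65 ± 0.50, adjusted p = 9.27e-04). F13A1, a subunit of a coagulation factor (-4.49 ± 1.03, adjusted p = 0.0125), and GPX3, a secreted glutathione peroxidase (-4.32 ± 1.07, adjusted p = 0.0175), were also among the falls. Without galectin-1 replicate 3 both lost their call (adjusted p up to 0.0702), and without galectin-1 replicate 1, vehicle replicate 1 or vehicle replicate 3 GPX3 did (0.0506, 0.0507 and 0.0523). The fit takes the spread of a gene from all 12 arrays, LPS arrays among them. F13A1 had an SD of 0.92 in galectin-1, 0.16 in vehicle and 2.98 in LPS arrays. Without LPS replicate 1 all 12 falls with galectin-1 kept their call, with adjusted p at most 3.44e-04.

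Of 19 dendritic cell maturation markers measured, 17 rose and 0 fell with galectin-1 (19 rose when adjusted over the list alone). TNFRSF9, a costimulatory receptor, rose by 3.91 ± 0.30, the cytokine receptor chain IL7R by 5.51 ± 0.59, CD80, a costimulatory ligand for T cells, by 2.65 ± 0.31, and CD274, the inhibitory ligand PD-L1, by 1.63 ± 0.17. The list as a whole was higher than other genes (median 2.57, camera adjusted p = 2.99e-18, adjusted p = 0.113 with an estimated correlation). Of 26 chemokines 12 rose and 0 fell (16 rose when adjusted over the list alone), among them CCL17, CCL4 and CCL8 at 3.49 ± 0.43, 2.81 ± 0.32 and 2.22 ± 0.24. Their median was 2.12 (adjusted p = 2.83e-10, adjusted p = 0.0566 with an estimated correlation). Among 32 cytokines 21 rose and 1 fell (22 and 2 over the list alone; median 1.72, adjusted p = 2.52e-11, adjusted p = 0.129 with an estimated correlation). IL1A rose by 4.33 ± 0.52. Among 33 feedback regulators and targets of the transcription factor NF-kB, 25 rose and 1 fell (26 and 2 over the list alone). TRAF1 rose by 3.22 ± 0.32 and CFLAR, an inhibitor of cell death, by 1.51 ± 0.17. That list had a median of 1.02 (adjusted p = 8.27e-15, adjusted p = 0.139 with an estimated correlation).

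Of 46 interferon-stimulated genes 43 rose and 0 fell (44 rose when adjusted over the list alone). ISG15, a ubiquitin-like modifier, rose by 3.80 ± 0.21, the guanylate-binding protein GBP1 by 3.24 ± 0.25, IFI44L by 5.51 ± 0.51 and the transcription factor IRF7 by 2.64 ± 0.23. Their median was 2.52 (adjusted p = 4.1e-39, adjusted p = 0.113 with an estimated correlation). Of 20 class I presentation genes 5 rose and 0 fell (6 over the list alone), among them the peptide transporter chains TAP1 (1.83 ± 0.28) and TAP2 (1.64 ± 0.23). The list test gave a median of 0.27 and adjusted p = 0.00865 (adjusted p = 0.504 with an estimated correlation), and 0.0522 without galectin-1 replicate 3. Of 19 class II presentation genes 0 rose and 3 fell, by either adjustment, with the lysosomal protease LGMN at -1.63 ± 0.35. Their median was -0.15, and the list test gave adjusted p = 0.118 (0.0319 with the donor number as a block, adjusted p = 0.657 with an estimated correlation and no block). CD1A, which presents lipid antigens, fell by 2.05 ± 0.39 (adjusted p = 0.0053) as 1 of 2 members lower among 5 CD1 genes, by either adjustment. The list had a median of -1.45 (adjusted p = 0.0717, 0.0338 with the donor block, adjusted p = 0.57 with an estimated correlation and no block). Of 24 uptake receptors of immature cells 5 rose and 5 fell (5 and 6 over the list alone; adjusted p = 0.878). The pattern receptor CLEC4E rose by 3.22 ± 0.38 and LY75, an endocytic receptor, by 1.85 ± 0.29, while the scavenger receptor CD36 fell by 2.73 ± 0.56 and ASGR2 by 1.68 ± 0.35.

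Of 30 matrix proteases and inhibitors 14 rose and 3 fell (14 and 3 over the list alone; median 0.60, adjusted p = 7.16e-04, adjusted p = 0.125 with an estimated correlation). The collagenase MMP1 rose by 5.24 ± 0.72, MMP7 by 4.31 ± 0.54 and ADAMDEC1 by 3.29 ± 0.42. TNC, the matrix glycoprotein tenascin C, rose by 4.11 ± 0.30 and the adhesion molecule PECAM1 fell by 2.30 ± 0.40 within the adhesion and migration list, where 11 of 44 rose and 7 fell (15 and 10 over the list alone; adjusted p = 0.264). Of 9 metallothioneins and related zinc genes 6 rose and 0 fell (7 over the list alone; median 2.30, adjusted p = 4.23e-04, adjusted p = 0.385 with an estimated correlation). MT2A rose by 3.17 ± 0.69. Glycolysis and hypoxia genes rose in 9 of 31 cases with 0 lower (12 over the list alone; median 0.43, adjusted p = 4.44e-05, adjusted p = 0.47 with an estimated correlation). The angiogenic factor VEGFA rose by 2.94 ± 0.46 and NDRG1 by 1.02 ± 0.18. Of 25 eicosanoid and tryptophan enzymes and receptors 8 rose and 2 fell (10 and 3 over the list alone; median 0.37, adjusted p = 0.00658, adjusted p = 0.241 with an estimated correlation). The lipoxygenase ALOX15B rose by 1.68 ± 0.22 and the prostaglandin receptor PTGER4 by 1.40 ± 0.17. Of 20 regulators of T cells 6 rose and 0 fell (8 over the list alone; median 0.62, adjusted p = 7.16e-04, adjusted p = 0.113 with an estimated correlation). The costimulatory ligand TNFSF9 rose by 2.13 ± 0.32 and the Notch ligand JAG1 by 1.43 ± 0.22. Of 40 transcription factors and signal regulators of dendritic cells 14 rose and 5 fell (21 and 7 over the list alone; median 0.39, adjusted p = 8.15e-04, adjusted p = 0.247 with an estimated correlation). SOCS3, a feedback inhibitor of cytokine signalling, rose by 3.99 ± 0.57 and BATF3 by 2.15 ± 0.26.

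Among 32 cell cycle genes 4 rose and 1 fell, by either adjustment. The cell cycle inhibitor CDKN1A rose by 1.41 ± 0.22 and the replication factor MCM5 by 0.81 ± 0.14. That list had a median of 0.35 (adjusted p = 0.0277, adjusted p = 0.129 with an estimated correlation) and its call was lost without galectin-1 replicate 2 or 3 (up to 0.0673). The remaining lists did not pass the list test in the galectin-1 comparison. Of 27 unfolded protein response genes 6 rose and 4 fell (7 and 7 over the list alone; adjusted p = 0.959), with DDIT4 at 3.01 ± 0.50 and the disulfide isomerase PDIA6 at -1.05 ± 0.23. The median was -0.09 while the mean was 0.08 and the test pointed up. Of 21 NRF2 target genes 2 rose and 4 fell (5 and 5 over the list alone; adjusted p = 0.938), among them GCLC, which makes a glutathione precursor, at -1.29 ± 0.26 and EPHX1 at -2.21 ± 0.48. The median was 0.03 and the test pointed up while the mean was -0.11. Heat shock genes gave 2 of 14 higher and 0 lower, by either adjustment (adjusted p = 0.211). The cochaperone DNAJA1 rose by 0.47 ± 0.10. Cholesterol synthesis gave 1 higher, LSS at 1.11 ± 0.20, and 1 lower, ACAT2 at -1.57 ± 0.31, of 18, by either adjustment (adjusted p = 0.144). Of 9 galectins and binding partners 1 rose and 1 fell, by either adjustment (adjusted p = 0.938), with the galectin-3 binding protein LGALS3BP at 2.13 ± 0.45. The mean was 0.15 while the median was -0.01 and the test pointed down.

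Markers of other blood cells did not pass the list test with galectin-1. Of 9 T cell, 10 NK cell and 6 erythroid markers 0 passed (list tests adjusted p = 0.518, 0.248 and 0.473). Of 10 B cell markers 1 rose and 1 fell (0.2), and of 9 platelet markers 1 rose, GP1BA at 2.37 ± 0.31 (0.712). Of 18 monocyte and macrophage markers 4 rose and 3 fell (5 and 7 over the list alone; 0.424), with S100A12 at 3.78 ± 0.63 and the lipid droplet protein PLIN2 at -1.57 ± 0.28. Of 9 neutrophil markers 1 rose and 3 fell (2 and 3 over the list alone; 0.518), with the receptor CSF3R at -1.18 ± 0.24. The GAPDH 3' to 5' ratio was 1.06 ± 0.0469 (SD, n = 3) in galectin-1 arrays against 1.03 ± 0.0328 in vehicle arrays. The count of 2301 fell to 1438 without galectin-1 replicate 2, 1421 without galectin-1 replicate 3, 1428 without vehicle replicate 2 and 1119 without vehicle replicate 3. By the fluidics station on which the arrays were stained, the median change of the called genes was 1.28 for those higher and -0.97 for those lower between the 1 galectin-1 array and the 3 vehicle arrays with no station recorded. It was 1.2 and -0.90 for the 2 galectin-1 arrays of the second station against those vehicle arrays, beside 1.24 and -0.93 over all arrays. The genes were called from these same arrays, so that the direction of these medians was built in. Arrays with no station recorded need not have shared a station.

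**Figure D1:**
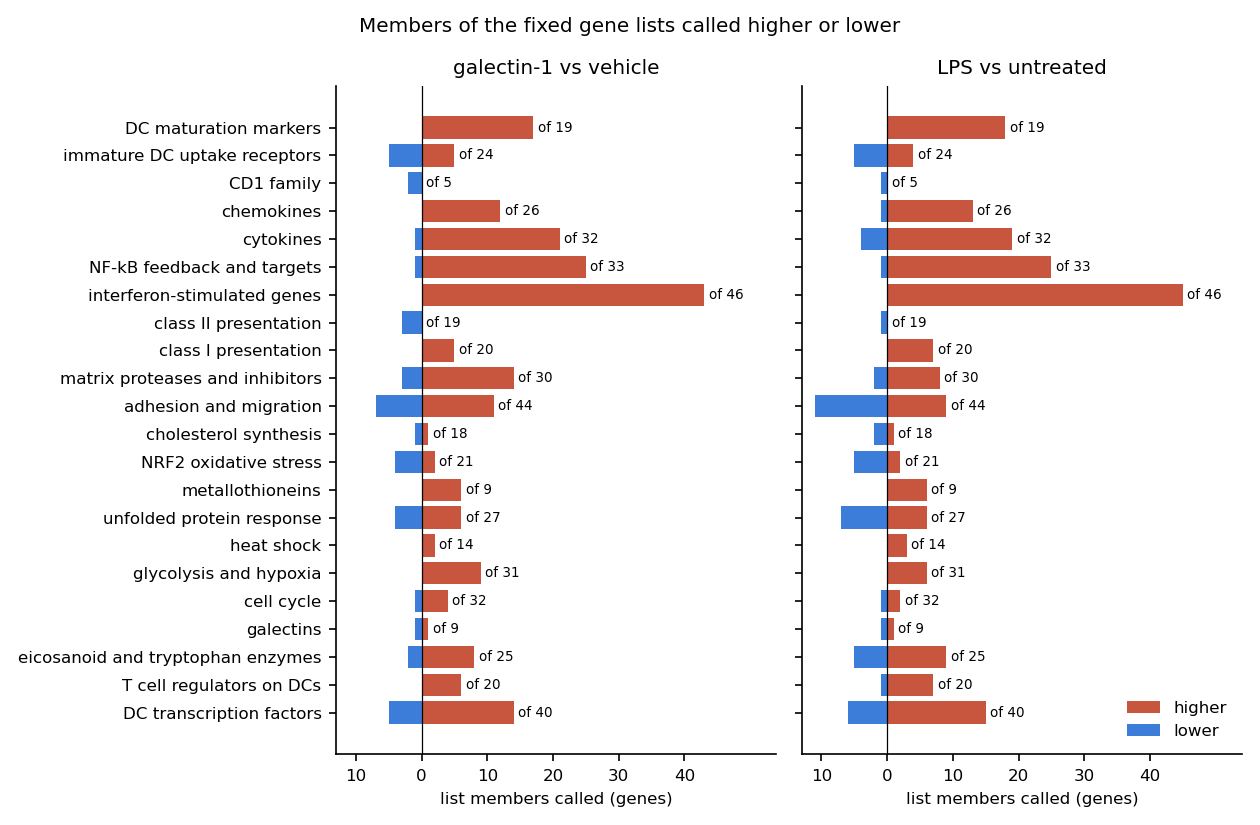
Members of the 22 gene lists of dendritic cell biology called higher (red, to the right) and lower (blue, to the left) in galectin-1 against vehicle arrays and in LPS against untreated arrays (x axis, number of genes; limma, adjusted p under 0.05); the number after each bar is the number of members measured. Interferon-stimulated genes gave 43 and 45 higher of 46.

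The comparison of LPS with untreated cells gives the response to the reference maturation stimulus. RSAD2, an antiviral enzyme induced by interferon, rose 199.5-fold (7.64 ± 0.57, standard error, n = 3 per group, adjusted p = 1.19e-05) and IFI27, another interferon-induced gene, 182.6-fold (7.51 ± 0.56, adjusted p = 1.19e-05). IDO1 rose by 7.30 ± 0.56 and IL1B by 6.30 ± 0.74 on the log2 scale (adjusted p = 1.19e-05 and 2.82e-04). SLC18A2, a vesicular monoamine transporter, fell by 3.31 ± 0.72 (adjusted p = 0.00969) and TLR4 by 1.39 ± 0.27 (adjusted p = 0.0061). LGALS1 differed by -0.16 ± 0.08 (adjusted p = 0.204).

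With LPS, 2532 genes (18.8%) passed, 1024 higher and 1508 lower, of which 1223 differed by at least 2-fold (605 higher and 618 lower), and 4302 had an unadjusted p under 0.05. The excess of falls was not stable. Centred on the array medians there were 1094 higher and 1138 lower, and in a fit of only the LPS and untreated arrays 595 and 423. Without LPS replicate 2 there were 535 and 443, and without LPS replicate 3, 501 and 391. TNFAIP6 (7.25 ± 0.29, adjusted p = 5.58e-08), IFI44L (6.91 ± 0.51), CD38 (6.88 ± 0.42), the adhesion receptor ADGRE1 (6.40 ± 0.48), EBI3 (6.37 ± 0.45), INHBA (6.35 ± 0.36), CCL5 (6.25 ± 0.47) and the heparan sulfate sulfotransferase HS3ST3B1 (6.17 ± 0.60) completed the 12 largest rises. The largest falls were those of SELENOP (-4.67 ± 1.42, adjusted p = 0.0379), GPX3 (-3.91 ± 1.07, adjusted p = 0.0251), F13A1 (-3.75 ± 1.03, adjusted p = 0.0261) and KCNJ5 (-3.68 ± 1.19, adjusted p = 0.0494). These sizes average unequal arrays. SELENOP had a level of 10.69 ± 4.14 (SD) and F13A1 of 13.34 ± 2.98 in LPS arrays, and without LPS replicate 1 they fell by 6.93 and 5.46. The transcription factor KLF4 (-3.33 ± 0.84, adjusted p = 0.0177) and the adhesion molecule CDH1 (-3.33 ± 0.81, adjusted p = 0.0156) came next. Of the 12 falls SLC18A2 alone kept its call without any 1 array. Without LPS replicate 2 or 3, 11 of them lost it (adjusted p up to 0.2 and 0.161), without untreated replicate 1, 2 or 3, 6, 7 and 8 did (0.128, 0.082 and 0.123). Without galectin-1 replicate 2 or 3, 2 and 1 did (0.0593 and 0.0541), and without vehicle replicate 1, 2 or 3, 2 each did (0.0668, 0.0646 and 0.0649). Without LPS replicate 1 all 12 kept it, with adjusted p at most 0.00138.

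Of the 19 maturation markers 18 rose and 0 fell with LPS (19 over the list alone; median 2.66, adjusted p = 1.46e-19, adjusted p = 0.113 with an estimated correlation). CD80 rose by 3.19 ± 0.31, CD274 by 2.23 ± 0.17 and TNFRSF9 by 3.06 ± 0.30. Of the 26 chemokines 13 rose and 1 fell (16 and 2 over the list alone; median 2.13, adjusted p = 1.93e-07, adjusted p = 0.11 with an estimated correlation). CCL4 rose by 3.55 ± 0.32 and CCL19, which attracts naive T cells, by 3.58 ± 0.47. Of the 32 cytokines 19 rose and 4 fell (21 and 4 over the list alone; median 1.56, adjusted p = 6.03e-10, adjusted p = 0.159 with an estimated correlation). IL18 rose by 3.12 ± 0.33. NF-kB feedback genes and targets gave 25 higher and 1 lower of 33 (26 and 2 over the list alone; median 1.19, adjusted p = 1.25e-18, adjusted p = 0.113 with an estimated correlation). TNFAIP3, a deubiquitinase that limits NF-kB, rose by 2.84 ± 0.28 and TRAF1 by 3.03 ± 0.32. Of the 46 interferon-stimulated genes 45 rose and 0 fell, by either adjustment (median 3.21, adjusted p = 2.95e-49, adjusted p = 0.113 with an estimated correlation). ISG15 rose by 4.06 ± 0.21 and GBP1 by 3.87 ± 0.25. Class I presentation gave 7 higher and 0 lower of 20 (9 over the list alone; median 0.19, adjusted p = 4.61e-04, adjusted p = 0.385 with an estimated correlation). TAP1 rose by 2.26 ± 0.28. Of 19 class II genes 0 rose and 1 fell, by either adjustment (median -0.28, adjusted p = 0.216). Of 5 CD1 genes 0 rose and 1 fell (2 over the list alone; median -1.50, adjusted p = 0.0664, 0.0221 with the donor block, adjusted p = 0.57 with an estimated correlation and no block). Uptake receptors gave 4 higher, such as CLEC4E at 4.00 ± 0.38, and 5 lower, such as the mannose receptor MRC1 at -1.19 ± 0.24, of 24 (4 and 8 over the list alone; adjusted p = 0.749).

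Of the 30 matrix proteases and inhibitors 8 rose and 2 fell with LPS (9 and 3 over the list alone; median 0.20, adjusted p = 0.0326, adjusted p = 0.327 with an estimated correlation), with ADAMDEC1 at 4.38 ± 0.42 and MMP7 at 3.46 ± 0.54. The list test gave 0.108 without untreated replicate 3. Metallothioneins gave 6 higher and 0 lower of 9, by either adjustment (median 2.10, adjusted p = 1.43e-04, adjusted p = 0.337 with an estimated correlation). Glycolysis and hypoxia genes gave 6 higher and 0 lower of 31, by either adjustment (median 0.31, adjusted p = 0.00145, adjusted p = 0.57 with an estimated correlation). ADM, which encodes a vasodilator peptide, rose by 2.65 ± 0.45 and VEGFA by 2.53 ± 0.46. Eicosanoid and tryptophan genes gave 9 higher and 5 lower of 25 (9 and 6 over the list alone; median 0.26, adjusted p = 0.0303, adjusted p = 0.337 with an estimated correlation), with PTGER4 at 2.19 ± 0.17 and KYNU, an enzyme of the kynurenine pathway, at 1.21 ± 0.13. That call was lost without untreated replicate 3 or LPS replicate 1 (up to 0.0822). Regulators of T cells gave 7 higher and 1 lower of 20 (8 and 1 over the list alone; median 0.46, adjusted p = 4.61e-04, adjusted p = 0.113 with an estimated correlation), with JAG1 at 1.81 ± 0.22. Transcription factors gave 15 higher and 6 lower of 40 (16 and 8 over the list alone; median 0.21, adjusted p = 0.00165, adjusted p = 0.289 with an estimated correlation). SOCS3 rose by 4.54 ± 0.57 and IRF1 by 1.69 ± 0.24. The adhesion list had 9 higher and 11 lower of 44 (10 and 13 over the list alone; adjusted p = 0.896), with ITGB8 at 5.89 ± 0.62. Its median, -0.02, differed in sign from its mean, 0.03, and from the test.

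The other lists did not pass with LPS. Cholesterol synthesis had 1 gene higher and 2 lower (2 and 3 over the list alone, adjusted p = 0.204). NRF2 targets had 2 higher and 5 lower (3 and 5 over the list alone, 0.469), and the unfolded protein response 6 and 7 (9 and 8 over the list alone, 0.379). Heat shock genes had 3 higher and 0 lower (4 and 2 over the list alone, 0.0867), the cell cycle 2 and 1 (2 and 0 over the list alone, 0.528) and galectins 1 and 1 (2 and 2 over the list alone, 0.923). The galectin list had a mean of 0.39 and a test pointing up beside a median of -0.08. Of the blood cell markers, monocyte and macrophage genes had 3 higher, such as S100A8 at 3.01 ± 0.55, and 2 lower (4 and 3 over the list alone, 0.961). Neutrophil genes had 0 higher and 3 lower (0.244) and platelet genes 1 higher and 0 lower (0.932). Of the T cell, B cell, NK cell and erythroid genes 0 were called (0.896, 0.473, 0.379 and 0.646). The T cell median and mean were -0.14 and -0.18 while the test pointed up. The GAPDH 3' to 5' ratio was 1.07 ± 0.0276 (SD, n = 3) in LPS arrays against 1.00 ± 0.0189 in untreated arrays. The count of 2532 fell to 1572, 1356 and 1547 without untreated replicate 1, 2 and 3, and to 978 and 892 without LPS replicate 2 and 3. With the station as a block it was 166. LPS replicate 1, stained on the station of the untreated arrays, gave medians of 0.76 and -0.45 over the genes called higher and lower, against 1.37 and -1.09 for LPS replicates 2 and 3 of the second station and 1.19 and -0.88 over all 3 LPS arrays. Here too the genes were called from these same arrays.

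**Figure D2:**
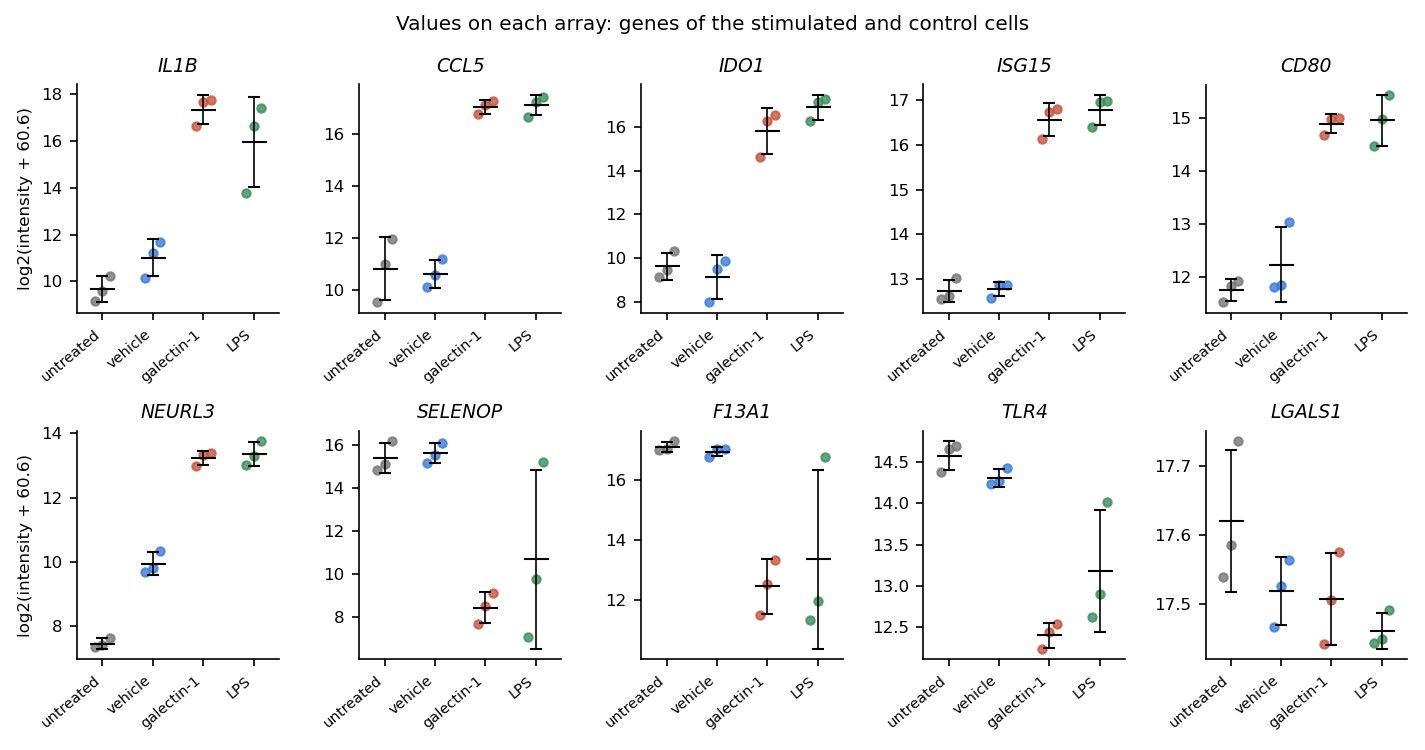
Values on each array (points, log2 of intensity + 60.6) in untreated, vehicle, galectin-1 and LPS cells, with the mean and SD of 3 arrays (bars), for genes that rose (upper plots), NEURL3, genes that fell, and LGALS1. NEURL3 had means of 7.46 in untreated, 9.94 in vehicle, 13.24 in galectin-1 and 13.35 in LPS arrays.

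The comparison of vehicle with untreated cells asks which transcripts differed between the controls of galectin-1 and of LPS. NEURL3, which encodes an E3 ubiquitin ligase, was higher in vehicle arrays by 2.48 ± 0.24 on the log2 scale, 5.60-fold (standard error, n = 3 per group, adjusted p = 0.00221). Its levels were 7.46 ± 0.16 (SD) in untreated and 9.94 ± 0.35 in vehicle arrays. It was the only gene of 13475 to pass in limma, against 555 at an unadjusted p under 0.05, fewer than a share of 0.05 of all genes. Its call was lost in a fit of only the vehicle and untreated arrays (adjusted p = 0.865), with the pseudocount of the median (0.0948) and with the station block (0.0872). INHBA at 1.47 ± 0.36 and G0S2, an inhibitor of lipid breakdown, at 1.09 ± 0.26 had adjusted p = 0.987 each. The cytokine TNF at 1.28 ± 0.41, TNFAIP3 at 0.99 ± 0.28 and CD274 at 0.62 ± 0.17 had adjusted p = 1. TLR4 differed by -0.27 ± 0.27 and LGALS1 by -0.10 ± 0.08 (adjusted p = 1 for both). Without vehicle replicate 2 the count was 2, the other gene being CCDC163 (-2.86, adjusted p = 0.0392), named after its values were seen.

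As groups, 4 lists lay higher in vehicle than in untreated arrays, each with 0 members called over all genes. These were maturation markers (median 0.33, camera adjusted p = 4.44e-05, adjusted p = 0.42 with an estimated correlation) and cytokines (0.18, adjusted p = 0.0023, adjusted p = 0.506 with an estimated correlation). The others were NF-kB feedback genes and targets (0.26, adjusted p = 1.43e-06, adjusted p = 0.385 with an estimated correlation) and metallothioneins (0.67, adjusted p = 0.0014, adjusted p = 0.42 with an estimated correlation), where MT1G differed by 1.46 ± 0.52 (adjusted p = 1). Adjusted over the list alone, 1 cytokine and 1 NF-kB gene passed, 1 each, both higher. Without untreated replicate 3 or vehicle replicate 1 the maturation and cytokine calls were lost (up to 0.17 and 0.106), and without vehicle replicate 2 the metallothionein call was (0.172). With the donor number as a block the NRF2 list was also higher (median 0.09, adjusted p = 0.0607 without and 0.0176 with the block, adjusted p = 0.657 with an estimated correlation and no block). The erythroid list was lower (median -0.57, adjusted p = 0.0638 without and 0.0314 with it, adjusted p = 0.247 with an estimated correlation and no block). With the fluidics station as a block all 4 lists turned to medians of -0.39, -0.44, -0.54 and -1.54, of which cytokines and NF-kB genes passed as lower (adjusted p = 0.0251 and 3.7e-04). No station was recorded for any vehicle array, so that an effect of the station stays open here. The GAPDH 3' to 5' ratio was 1.03 ± 0.0328 (SD, n = 3) in vehicle against 1.00 ± 0.0189 in untreated arrays.

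Galectin-1 set against untreated cells uses the control of the LPS comparison and takes in any difference between vehicle and untreated cells. IL1B rose 207.7-fold (log2 fold change 7.70 ± 0.74, standard error, n = 3 per group, adjusted p = 6.2e-05), MMP1 172.0-fold (7.43 ± 0.72, adjusted p = 6.33e-05), INHBA by 7.23 ± 0.36 and TNIP3, an inhibitor of NF-kB activation, by 6.35 ± 0.94. KCNJ5 (-5.58 ± 1.19, adjusted p = 0.00704), ADORA3 (-4.60 ± 0.82, adjusted p = 0.0029), P2RY13 (-4.26 ± 0.84, adjusted p = 0.00497) and TLR4 (-2.17 ± 0.27, adjusted p = 3.89e-04) fell. LGALS1 differed by -0.11 ± 0.08 (adjusted p = 0.377). In all, 2660 genes (19.7%) passed, 1136 higher and 1524 lower, 1367 of them by at least 2-fold (663 and 704), and 4391 at an unadjusted p under 0.05. The share of higher calls was 42.7%, and 53.9% when the arrays were centred on their medians, which moved the median change of all genes from -0.09 to 0.03.

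Of the lists, 12 were higher in galectin-1 than in untreated arrays and 0 lower. All 19 maturation markers rose, by either adjustment (median 2.75, adjusted p = 1.22e-20, adjusted p = 0.113 with an estimated correlation), with CD80 at 3.12 ± 0.31. Of 46 interferon-stimulated genes 43 rose (45 over the list alone; 2.70, adjusted p = 4.1e-39, adjusted p = 0.113 with an estimated correlation). Of 33 NF-kB genes 24 rose and 1 fell (26 and 1 over the list alone; 1.11, adjusted p = 1.25e-18, adjusted p = 0.113 with an estimated correlation), and of 32 cytokines 22 rose and 2 fell (23 and 2 over the list alone; 2.04, adjusted p = 7.07e-13, adjusted p = 0.113 with an estimated correlation). Chemokines had 14 of 26 higher and 0 lower (16 and 1 over the list alone; 2.40, adjusted p = 2.42e-10, adjusted p = 0.0566 with an estimated correlation), with CCL5 at 6.19 ± 0.47. Metallothioneins had 7 of 9 higher (8 over the list alone; 3.00, adjusted p = 5.24e-06, adjusted p = 0.247 with an estimated correlation). MT1G rose by 3.18 ± 0.52. Matrix proteases had 12 higher and 3 lower of 30 (14 and 4 over the list alone; 0.74, adjusted p = 1.68e-04, adjusted p = 0.113 with an estimated correlation). Glycolysis and hypoxia genes had 8 higher and 1 lower of 31 (11 and 1 over the list alone; 0.44, adjusted p = 1.8e-04, adjusted p = 0.513 with an estimated correlation), and a median of -0.11 with the station as a block. Regulators of T cells had 7 higher and 1 lower of 20 (9 and 1 over the list alone; 0.58, adjusted p = 3.22e-04, adjusted p = 0.113 with an estimated correlation), and transcription factors 16 higher and 5 lower of 40 (19 and 8 over the list alone; 0.39, adjusted p = 8.69e-04, adjusted p = 0.247 with an estimated correlation). Eicosanoid and tryptophan genes had 9 higher and 4 lower of 25 (12 and 4 over the list alone; 0.60, adjusted p = 0.00165, adjusted p = 0.159 with an estimated correlation), with PTGER4 at 1.98 ± 0.17. Class I genes had 6 higher and 0 lower of 20 (8 and 2 over the list alone; 0.25, adjusted p = 0.0111, adjusted p = 0.513 with an estimated correlation, and 0.0539 without galectin-1 replicate 3). With the donor block the CD1 list (median -1.63, adjusted p = 0.0717 without and 0.0314 with the block) and the class II list (-0.29, 0.0647 and 0.0128) were lower, each with adjusted p = 0.57 with an estimated correlation and no block. The count of 2660 was 1772 without untreated replicate 1, 1736 without untreated replicate 2 and 19 with the station as a block. Galectin-1 replicates 1 and 2 were on another station than the untreated arrays, and for galectin-1 replicate 3 none was recorded.

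The responses to galectin-1, against vehicle, and to LPS, against untreated cells, share no array, so that their overlap holds no shared control. They do share the donors and, in the fit, 1 spread per gene. Their calls can thus coincide more often than those of independent lists. Of the genes that rose, 708 were called in both, where independent lists of 1022 and 1024 among 13475 genes would share 77.7, and of those that fell 868, where 143 would be shared. Called in both, 0 genes went in opposite directions. Over the 3257 genes called in either, 96.7% had the same sign, and the log2 fold changes correlated across genes with r = 0.913 and a slope of 0.936 for LPS on galectin-1. Over all genes r was 0.768, rho was 0.648 and 74.8% had the same sign. Genes are not independent replicates, so that no p is given. IDO1, TNFAIP6, CD38, EBI3, INHBA, IL1B, CCL5 and IFI44L stood among the 12 largest rises of both responses, and SELENOP, KCNJ5, F13A1, GPX3 and the dipeptidase DPEP2 among the 12 largest falls of both.

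**Figure D3:**
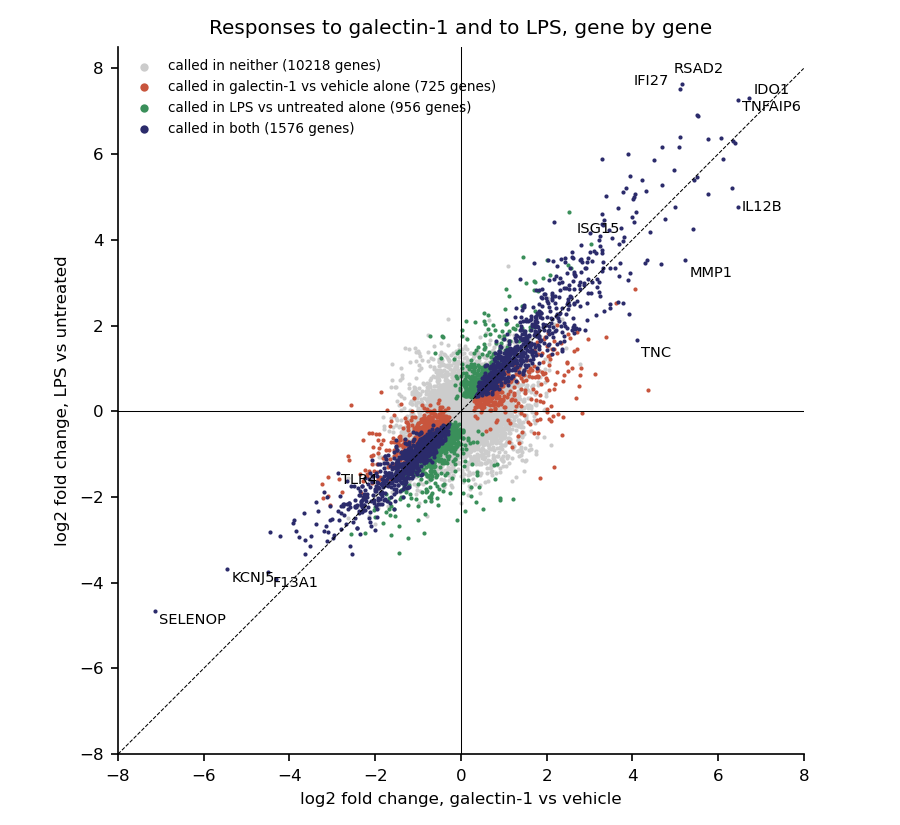
Log2 fold change of each of 13475 genes (points) for galectin-1 against vehicle (x axis) and LPS against untreated cells (y axis), coloured by the comparison in which the gene was called; the dashed line marks equal responses. The 1576 genes called in both lie in the upper right and lower left, and TNC and MMP1 lie below the line.

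The direct comparison of galectin-1 with LPS sets the stimuli side by side. The stimuli were taken to have different controls. On that reading the direct comparison also holds any effect of the vehicle, which only the difference of effects takes away. TNC was higher with galectin-1 by 2.57 ± 0.30 on the log2 scale, 5.92-fold (standard error, n = 3 per group, adjusted p = 0.0233). Its levels were 12.51 ± 0.21 (SD) in galectin-1 and 9.95 ± 0.09 in LPS arrays. It was the 1 gene of 13475 to pass, against 748 at an unadjusted p under 0.05, near a share of 0.05 of all genes. The matrix metalloproteases MMP12, MMP1 and MMP10 differed by 4.28 ± 0.70, 3.91 ± 0.72 and 3.25 ± 0.67 without passing (adjusted p = 0.135, 0.21 and 0.34). So did CSF1, a growth factor of macrophages (2.32 ± 0.42, adjusted p = 0.21), and CCL24, a chemokine that attracts eosinophils (2.01 ± 0.31, adjusted p = 0.126). The mean levels of MMP12, MMP1 and MMP10 were 13.08, 10.04 and 9.21 in vehicle against 11.71, 7.85 and 7.30 in untreated arrays, differences that did not pass there. TLR4 differed by -0.77 ± 0.27 (adjusted p = 0.825) and LGALS1 by 0.05 ± 0.08 (adjusted p = 0.999). The TNC call was lost without untreated replicate 1 (adjusted p = 0.0566), galectin-1 replicate 1, 2 or 3 (0.266, 0.122 and 0.0599), LPS replicate 2 or 3 (0.0947 and 0.142) or vehicle replicate 2 (0.0527). Without LPS replicate 1 there were 19 calls. Without vehicle replicate 3 the count was 2, TNC and CSF1.

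With the donor number as a block, 11 genes passed between galectin-1 and LPS, against 0 in the difference of effects with the same block. TNC, MMP12 (4.28 ± 0.51, adjusted p = 0.0119 for both), CSF1 (adjusted p = 0.0193), CCL24 (0.0321) and MMP10 (0.0452) were higher with galectin-1. So were the activating receptor TREM1 (2.13 ± 0.25, adjusted p = 0.0119), the GTPase RAC2 (0.86 ± 0.12, 0.0321), IL1RAP, a cytokine receptor chain (1.61 ± 0.20, 0.0184), and SLC27A3 (1.74 ± 0.25, 0.0321). NUPR1, a stress-induced regulator of transcription (-1.60 ± 0.18, adjusted p = 0.0119), and MPP1 (-0.87 ± 0.12, 0.0321) were lower. IL1RAP, SLC27A3, NUPR1 and MPP1 were named after their values were seen. Within the second station, which held 2 arrays of each stimulus, 0 genes passed in limma, against 1466 at an unadjusted p under 0.05. The arrays were galectin-1 replicates 1 and 2 and LPS replicates 2 and 3. Only donor 2 was in both groups, so that these values also hold differences between donors. TNC differed by 2.49, CSF1 by 2.56 and CCL24 by 2.58, each with adjusted p = 0.0597.

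Between the stimuli, interferon-stimulated genes were lower with galectin-1 as a list (median -0.49, camera adjusted p = 7.43e-13, adjusted p = 0.408 with an estimated correlation), with 0 of 46 called by either adjustment. IFIT2, an antiviral protein, differed by -1.51 ± 0.62 (adjusted p = 0.835). Matrix proteases were higher (median 0.15, mean 0.65, adjusted p = 3.71e-04, adjusted p = 0.113 with an estimated correlation), with 0 called over all genes and 4 higher when adjusted over the list alone. Cytokines were higher (median 0.29, adjusted p = 4.95e-04, adjusted p = 0.42 with an estimated correlation; 0 called, 7 over the list alone), with TNFSF14, a costimulatory ligand, at 2.36 ± 0.55 (adjusted p = 0.427). In limma TNFSF14 passed without LPS replicate 1 (3.15, adjusted p = 0.0167) and with the station block (3.16, adjusted p = 0.0131), but not with the donor block. NRF2 targets (0.14, adjusted p = 7.16e-04, adjusted p = 0.42 with an estimated correlation; 0 called, 2 over the list alone) and cell cycle genes (0.21, adjusted p = 0.0116, adjusted p = 0.113 with an estimated correlation; 0 called) were higher. So were maturation markers (0.13, adjusted p = 0.0203, adjusted p = 0.657 with an estimated correlation; 0 called, 1 over the list alone) and metallothioneins (0.55, adjusted p = 0.0234, adjusted p = 0.57 with an estimated correlation; 0 called). Without LPS replicate 1 the list tests gave 0.475 for cytokines, 0.128 for the cell cycle, 0.832 for metallothioneins and 0.928 for maturation markers, whose test then pointed down. Without galectin-1 replicate 3 the calls of the cell cycle, maturation and metallothionein lists were also lost, without galectin-1 replicate 2 that of metallothioneins, and without LPS replicate 2 that of NRF2 targets (0.0862). With the donor block 5 more lists passed. Uptake receptors (median 0.20, adjusted p = 0.118 without and 0.0394 with the block), chemokines (0.32, 0.0732 and 0.0319; 2 higher over the list alone) and adhesion genes (0.06, 0.132 and 0.0485; 3 higher over the list alone) were higher with galectin-1. Class I genes (-0.09, 0.0922 and 0.0448) and monocyte and macrophage markers (-0.13, 0.112 and 0.0357) were lower. With an estimated correlation and no block the adjusted p of these 5 lists was 0.289, 0.42, 0.42, 0.657 and 0.538.

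**Figure D4:**
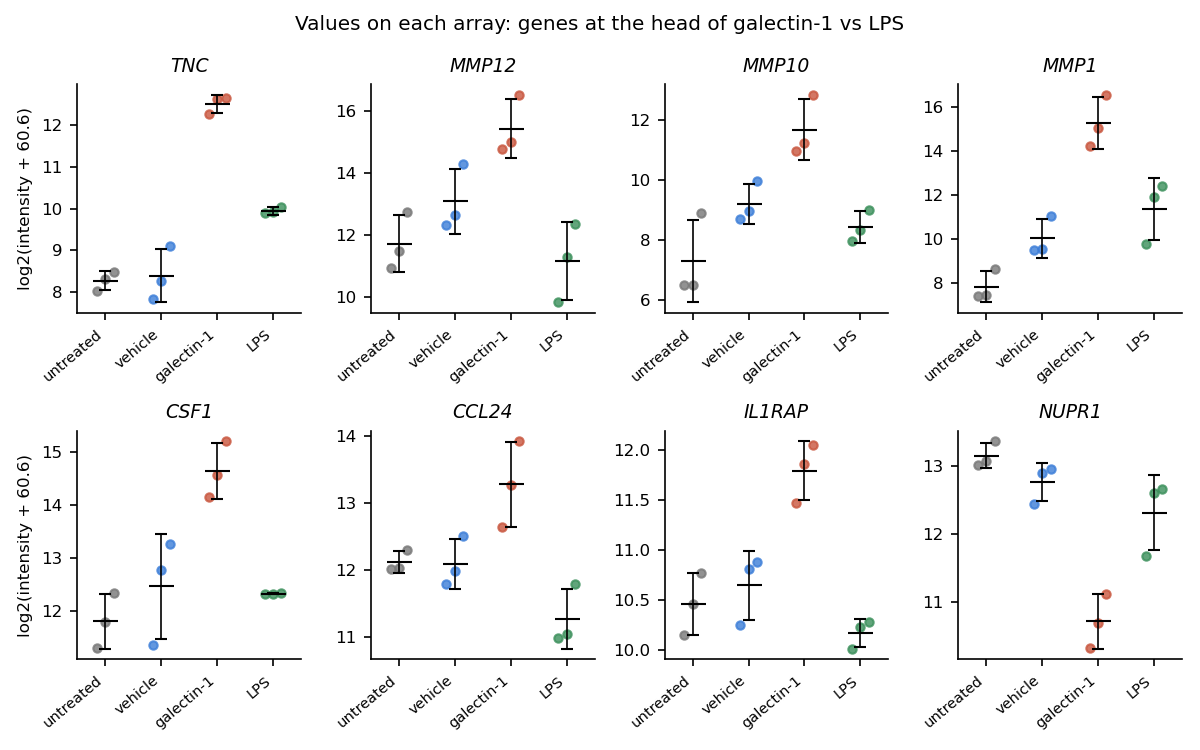
Values on each array (points, log2 of intensity + 60.6) with the mean and SD of 3 arrays (bars) for 8 genes with the smallest p-values or the donor-block calls in galectin-1 against LPS. TNC had a mean of 12.51 in galectin-1 and 9.95 in LPS arrays, and the 2 sets of values did not overlap.

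The difference of effects, the change from vehicle to galectin-1 minus the change from untreated to LPS, tests whether each stimulus moved a gene from its own control by a different amount. In limma 0 of 13475 genes passed, and 0 with the donor number as a fixed block. At an unadjusted p under 0.05 there were 585, fewer than a share of 0.05 of all genes. The genes with the smallest p were NEURL3 (-2.59 ± 0.33, standard error, n = 3 per group, adjusted p = 0.0582, or 0.0361 with the donor number as a random block), TNC (2.44 ± 0.43, 0.603), LACC1, an immunometabolic enzyme (-1.05 ± 0.20, 0.857), the replication factor GINS2 (3.49 ± 0.71, 0.999) and DNAJC22 (2.04 ± 0.43, 0.999). TLR4 (-0.50 ± 0.39) and LGALS1 (0.15 ± 0.11) had adjusted p = 0.999 each. Interferon-stimulated genes (median -0.56, adjusted p = 2.11e-11, adjusted p = 0.42 with an estimated correlation) and NF-kB genes (-0.16, adjusted p = 0.0132, adjusted p = 0.657 with an estimated correlation) were lower as lists. Cell cycle genes were higher (0.25, adjusted p = 0.0224, adjusted p = 0.125 with an estimated correlation), with 0 members called. Matrix proteases did not pass (median 0.09, adjusted p = 0.118, adjusted p = 0.455 with an estimated correlation). Adjusted over the list alone, 2 chemokines and 2 adhesion genes were higher. The NF-kB call was lost without any of untreated replicate 2, galectin-1 replicate 1, LPS replicate 2 or 3 or vehicle replicate 1 or 2 (adjusted p up to 0.629). With the station as a block the interferon and NF-kB lists turned and passed as higher (median 0.24, adjusted p = 0.0403, and 0.23, adjusted p = 0.00314). The cell cycle call was lost without untreated replicate 3, galectin-1 replicate 2 or 3 or LPS replicate 1 (up to 0.129). With the donor block the adhesion list (median 0.16, adjusted p = 0.0647 without and 0.0108 with the block) and the erythroid markers (0.67, 0.0576 and 0.0319) were higher and the monocyte and macrophage markers lower (-0.26, 0.159 and 0.0485). With an estimated correlation and no block the adjusted p of these lists was 0.339, 0.247 and 0.573.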

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

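The counts over other splits of the arrays were planned, while the tests of the 3 patterns below were chosen only after the result was seen. Among the 4527 kept probe sets that name no gene, which entered no gene count, limma called 240 in galectin-1 against vehicle, 275 in LPS against untreated and 278 in galectin-1 against untreated arrays, against 0 in vehicle against untreated. They were listed as signal in data that no gene comparison used. Their share was lower than that of all 31891 kept probe sets, of which 3924, 4281 and 4583 were called in the same comparisons.

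LPS replicate 1 lay between the untreated and the other LPS arrays. Shares were taken over genes called with a large change for the other stimulus and also changed in replicates 2 and 3 of the same stimulus. LPS replicate 1 reached a median share of 0.395 of the response of LPS replicates 2 and 3 over 221 rising genes (quartiles 0.23 and 0.542). Over 130 falling genes the share was 0.477 (quartiles 0.366 and 0.565). The array weight of LPS replicate 1, 0.373, was the lowest of the 12. A weak response of the same cells to any stimulus was argued against for the falling genes. Galectin-1 replicate 1 reached a median of 0.978 of the galectin-1 response over 115 falling genes (quartiles 0.887 and 1.06). That set rests on the LPS call, in which LPS replicate 1 took part. It may thus favour genes to which donor 1 responded, and it is not the set used for LPS replicate 1. For the rising genes a weak response stays open. Galectin-1 replicate 1 reached 0.682 over 235 rising genes of the galectin-1 response (quartiles 0.418 and 0.969), a range that overlaps that of LPS replicate 1. Unstimulated cells or RNA mixed into LPS replicate 1 may account for the pattern but would need 1 share for every gene. The medians of falling and rising genes differed by 0.0818 (bootstrap interval over genes 0.0326 to 0.14). The median share was 0.555 for maturation markers and 0.226 for cytokines. The bootstrap took the genes of 1 array as independent, so that its interval holds no spread between arrays or donors. Spread between donors leaves such mixing open. The fluidics station cannot be told apart from mixing, because LPS replicate 1 was the 1 LPS array on the station of the untreated arrays.

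Galectin-1 and LPS changed largely the same genes, with r = 0.913 over genes called in either. Endotoxin in the galectin-1 preparation might give such a correlation, as might a shared pathway, and the series held no group that could part them. A single response at 2 strengths would shift every list the same way, whereas the matrix protease list was on average 0.65 higher on the log2 scale with galectin-1 and the interferon list lower. Protease means were 13.25 to 13.48 on galectin-1 and 12.56 to 12.83 on LPS arrays, while interferon means overlapped, at 13.66 to 14.24 and 13.96 to 14.88. Within the same-numbered pairs proteases were higher in all 3, by a mean of 0.65 (95% interval 0.57 to 0.74), and interferon-stimulated genes lower in all 3, by a mean of -0.54. The interval of the interferon difference, -1.08 to 0.01, held 0, so that a single response at 2 strengths stays open. These differences also hold that of the controls. Against the control of each stimulus, the protease list had a mean change of 1.06 with galectin-1 and 0.52 with LPS. In the difference of effects, which takes the controls away, the protease list did not pass (median 0.09, camera adjusted p = 0.118, adjusted p = 0.455 with an estimated correlation). That median is not to be set against the mean of 0.65, since medians and means of this list differed.

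Vehicle arrays were shifted towards the stimulated profile. Over 94 genes at least 8-fold higher with galectin-1 than with vehicle, the median of vehicle minus untreated was 0.28 and 68.1% lay above 0, against -0.03 and 45.1% of all genes. Carry-over of stimulated cells or RNA into the vehicle samples, as the whole of the NEURL3 difference, would bring 1 share for every gene. NEURL3 needed a share of 8.67% galectin-1 material (6.79 to 11.74% by array), and the other 93 genes a median of 0.675% (quartiles -0.911 and 1.92%, highest 7.60%). In each vehicle array the NEURL3 share lay above the upper quartile of the others, also with LPS arrays as the material. However, NEURL3 was picked as the 1 gene called between vehicle and untreated arrays, so that a share above most others was built in. Carry-over of the size NEURL3 needed is argued against by the other 93 genes as a set, with an upper quartile of 1.92%. Those genes were picked as higher with galectin-1 than with vehicle, which favours low shares and was not allowed for. A smaller share, with a NEURL3 value raised by the choice of that gene, stays open. For the smaller shift of the other genes carry-over may be the source. It would again need 1 share, and the medians were 2.37% for NF-kB genes and 0.38% for interferon-stimulated genes, a difference that was not tested. A response to the vehicle or its handling was not tested and stays open, as does the fluidics station, since 0 vehicle arrays had a station recorded.

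With 3 arrays against 3 there are 10 splits, which cannot give a share under 0.05. For galectin-1 against vehicle 1 split, the real one, gave as many as 2301 genes and the highest other gave 0. For LPS against untreated it was 1 split, with 2532 genes and 0 in the highest other, and for galectin-1 against untreated 1 split, with 2660 and 0. For vehicle against untreated 2 of 10 splits gave as many as the real count of 1, and the highest other gave 1, also among the 4 splits that part all 3 pairs. For galectin-1 against LPS 2 of 10 splits gave as many as the real count of 1, and the highest other gave 170, against 0 among the other splits that part all 3 pairs. That split set galectin-1 replicates 1 and 2 and LPS replicate 1 against galectin-1 replicate 3 and LPS replicates 2 and 3. On the first principal component the first set lay at 1.16 to 49.3 and the second at 55.5 to 65.7. The untreated and vehicle arrays lay at -48.4 to -38.3. The split thus followed the order of the stimulated arrays away from the controls, with LPS replicate 1 nearest to them. What sets this order was not tested. For the difference of effects all 10 splits gave as many as the real count of 0, with 585 genes at an unadjusted p under 0.05 in limma, fewer than a share of 0.05 of all genes.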

How the results depend on the processing

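The donor block without LPS replicate 1 was added after the data were seen, and the other alternatives were planned. The fixed donor block raised the counts of called genes to 2938 for galectin-1 against vehicle, 3228 for LPS against untreated, 3335 for galectin-1 against untreated and 11 for galectin-1 against LPS. It ended 0 list calls, added the 15 given beside the lists, and changed the call of no gene named in the report other than those given there. None of the 129 calls of named genes changed direction under an alternative that tested it, 88 of them being tested with the filter on all arrays and all under the others, and 97 of 3313 values did not pass, mostly under the station block or with an array left out. The station block took the 4 arrays with no station recorded as a station of their own. Under it vehicle arrays were set against galectin-1 replicate 3, untreated arrays against LPS replicate 1, and the stimuli against each other on the 4 arrays of the second station. Those 4 arrays were galectin-1 replicates 1 and 2 and LPS replicates 2 and 3, so that the donors differed in part. The block's values for vehicle against untreated and the related comparisons join these steps, each resting on 1 or 2 arrays of a stimulus. They thus hold differences between single arrays and donors beside any effect of the station. Except where said otherwise, the cause was not tested.

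For galectin-1 against vehicle, the 2-fold minimum left 1192 genes by its construction, the added block gave 3460, and leaving out 1 array gave 1119 to 2861. For LPS against untreated, the 2-fold minimum left 1223, the fit of only the 2 groups gave 1018, the station block 166, the added block 4057 and leaving out 1 array 892 to 3700; with the station block the comparison rests on LPS replicate 1 alone, the only LPS array on the station of the untreated arrays. For galectin-1 against untreated, the 2-fold minimum left 1367, the station block gave 19 and leaving out 1 array 1736 to 3241. For vehicle against untreated, 0 genes passed with the pseudocount of the median, 0 with the filter on all arrays, where NEURL3 was not tested, and 0 with only the 2 groups, 174 passed with the station block, 2 with the added block (NEURL3 and SGPP2, chosen after its values were seen, 1.30) and 1 to 2 with 1 array left out. The adjusted p of NEURL3 ran from 0.000651 to 0.865 over 25 alternatives, 22 of which called it.

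For galectin-1 against LPS, 11 genes passed with the donor block, 0 with a pseudocount of 1, 0 without a filter and 0 with the filter on all arrays, where TNC was not tested. There were 68 with the station block, 84 with the added block and 0 to 19 with 1 array left out. With TNC the 2 calls were those of IL1RAP with the random block, TENT5A (-1.38) with the mean of probe sets and CCL24 with array weights, TENT5A and IL1RAP being named after their values were seen. The adjusted p of TNC ran from 0.000907 to 0.266 over 25 alternatives, 16 of which called it. In the difference of effects NEURL3 was the 1 gene called with the random block (adjusted p = 0.0361), a pseudocount of 1 (-3.10, 0.0194), quantile normalization (0.0394), median centring (0.03), the mean of probe sets (0.038) and array weights (0.0443); 35 genes passed with the station block, 25 with the added block and 0 to 0 with 1 array left out.

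The estimated correlation left 0 lists past the threshold in every comparison, from 13 for galectin-1 against vehicle, 12 for LPS against untreated, 4 for vehicle against untreated, 12 for galectin-1 against untreated, 7 for galectin-1 against LPS and 3 for the difference of effects. For vehicle against untreated there were 10 with the station block, 7 with the added block and 3 to 8 with 1 array left out; for galectin-1 against LPS 12 with the donor block and 6 to 11 with 1 array left out; for the difference of effects 6 with the donor block, 11 with the station block, 7 with the added block and 3 to 5 with 1 array left out.

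With the station block, which joins vehicle and untreated arrays only by way of the stimulated arrays, 4 lists of that comparison reversed, to medians of -0.39 for maturation markers, -0.44 for cytokines, -0.54 for NF-kB genes and -1.54 for metallothioneins, as did INHBA (-0.28), TNFAIP3 (-0.30), CD274 (-0.10), MT1G (-0.35) and TLR4 (0.93), of which none had passed. Glycolysis genes in galectin-1 against untreated went to -0.11, and in the difference of effects NF-kB genes went to 0.23 and interferon-stimulated genes to 0.24. Of these reversed lists, 4 passed in the opposite direction: cytokines (adjusted p = 0.0251) and NF-kB genes (3.7e-04) in vehicle against untreated, and NF-kB genes (0.00314) and interferon-stimulated genes (0.0403) in the difference of effects. The test of maturation markers in galectin-1 against LPS pointed down with the station block (median 0.11), without LPS replicate 1 (0.0316, the range with 1 array left out being 0.0316 to 0.311) and with the added block (-0.12). LGALS1, close to 0 in every comparison, changed sign in galectin-1 against vehicle with quantile normalization (0.0346), median centring (0.0459), the station block (0.0562) and with 1 array left out (-0.0450 to 0.0214), and in galectin-1 against untreated with quantile normalization (0.0149) and median centring (0.000153). Signal over background limits dim genes most: a pseudocount of 1 in place of 60.6 moved NEURL3 in vehicle against untreated from 2.48 to 2.99.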

Other observations

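The gene families below were chosen only after the data were seen, as 64 tests of 16 families in 4 comparisons. Subunits of the proteasome, which makes peptides for class I presentation, rose in 15 of 41 cases with 0 lower in galectin-1 against vehicle (median 0.29, camera adjusted p = 1.94e-06, adjusted p = 0.662 with an estimated correlation) and in 19 with 2 lower in LPS against untreated (0.37, adjusted p = 1.06e-06, adjusted p = 0.662 with an estimated correlation). Subunits of complex I of the respiratory chain fell in 17 of 32 cases with 1 higher in the galectin-1 comparison (-0.45, adjusted p = 2.84e-06, adjusted p = 0.662 with an estimated correlation) and in 22 with 0 higher in the LPS comparison (-0.56, adjusted p = 4.36e-08, adjusted p = 0.662 with an estimated correlation). Of 58 cytosolic ribosomal protein genes 10 fell and 0 rose with galectin-1 (-0.22, adjusted p = 1.94e-06, adjusted p = 0.699 with an estimated correlation) and 29 fell and 0 rose with LPS (-0.33, adjusted p = 1.47e-10, adjusted p = 0.662 with an estimated correlation).

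Of 29 interleukin receptor chains 10 rose and 2 fell with galectin-1 (median 0.47, adjusted p = 0.0015, adjusted p = 0.662 with an estimated correlation) and 8 rose and 2 fell with LPS (0.35, adjusted p = 0.0159, adjusted p = 0.662 with an estimated correlation). IL15RA, which presents a T cell growth factor to neighbouring cells, rose by 3.68 ± 0.38 with galectin-1 and 3.90 ± 0.38 with LPS (standard error, n = 3 per group). The direction of these 4 family medians was the same with quantile normalization and median centring, and without any 1 array their calls stayed under an adjusted p of 0.0459 at most. In vehicle against untreated arrays 0 of their members were called in limma.

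Of the other families, 366 zinc finger genes had 1 higher and 36 lower with galectin-1 (median -0.29, adjusted p = 3.76e-04, adjusted p = 0.662 with an estimated correlation). With LPS 5 were higher and 32 lower (median -0.24, camera adjusted p = 0.0576). Purinergic receptors (-1.64, adjusted p = 0.0302, adjusted p = 0.662 with an estimated correlation) and aldehyde dehydrogenases (-0.51, adjusted p = 0.0475, adjusted p = 0.662 with an estimated correlation) were lower with galectin-1, and lost their calls on leaving out 2 and 6 of the 12 arrays. With LPS their medians were -1.50 and -0.45 without passing (camera adjusted p = 0.229 and 0.285). Of 10 purinergic receptors 1 rose and 5 fell in each of these comparisons. With LPS, leukocyte immunoglobulin-like receptors were higher (0.88, adjusted p = 0.0108, adjusted p = 0.662 with an estimated correlation), with 4 of 10 called. With galectin-1 4 of 10 were called higher as well, while the family did not pass (median 0.65, camera adjusted p = 0.191). Between galectin-1 and LPS 4 families passed with 0 members called. Mitochondrial ribosomal proteins (0.13, adjusted p = 2.84e-06, adjusted p = 0.662 with an estimated correlation) were higher with galectin-1. So were cytosolic ribosomal proteins (0.09, adjusted p = 3.54e-04, adjusted p = 0.708 with an estimated correlation) and complex I subunits (0.10, adjusted p = 3.76e-04, adjusted p = 0.708 with an estimated correlation). Toll-like receptors were lower (-0.42, adjusted p = 0.0179, adjusted p = 0.662 with an estimated correlation). The last 3 lost their calls on leaving out 2 of the 12 arrays each.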
